A study of Mus musculus with 49 samples.

How the data were processed

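T cell receptor beta chain (TRB) rearrangements were sequenced from genomic DNA of peripheral blood mononuclear cells of MMTV-PyMT mice, which develop mammary tumours from a mammary-specific viral transgene. The labels list 49 samples, of which 18 had a deposited clonotype table; the other 31, among them the untreated and wild-type samples, were not analysed here. Each library came from 1 mouse. Per the labels, PLX3397 (pexidartinib, an inhibitor of the receptor CSF1R) was given in chow at 40 mg/kg per day from day 80 of age. Paclitaxel (PTX) was injected at 10 mg/kg every 5 days from day 85, and an antibody against PD-1 was given from day 87 at 1.0 mg and then 0.5 mg per mouse. Blood was taken at d95 or d105. The labels do not link samples of d95 to samples of d105, so each sample was treated as a separate mouse. The triple-treated mice carry the letters R or NR in their labels. The labels do not spell these out, and they were read as responder and non-responder.

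Each deposited table lists clonotypes with V and J segments, CDR3 sequences and several columns of abundance. The deposited read count is a count of whole reads per clonotype, with no molecular identifiers. The authors also deposited 2 normalized versions of this count, which are scores of whole numbers and not reads. The later of these columns was used for all main values, chosen after the columns were seen and before any test was run; the other normalized column and the read counts were alternatives. The deposited read fraction is a fraction of a read total that was larger than the sum of the listed clonotypes in some libraries. The aligner, its version, the germline reference and the genome build are not stated, nor is how the normalization factors were made. All 43235 listed clonotypes were productive. Of these, 40810 had a normalized count above 0, with 5818 of 6524 in R mouse 2 of d95. The others did not enter the values by normalized counts or with each clonotype counted once. A comparison of the normalized and read columns, over clonotypes with at least 100 reads, gave 1 factor per V and J pair. In the 129 pairs present in several libraries this factor differed between libraries by at most 0.00845. The factors ranged from 0.292 to 11.0 over 162 pairs, with a median of 1.02.

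Clonality (1 minus Shannon entropy over the log of the number of clonotypes), rarefied richness, the share of the 10 largest clonotypes and the mean CDR3 length were computed per mouse. Rarefied richness was the number of clonotypes expected at 33174 counts, from the analytic formula. They were compared by two-sided exact permutation tests of the difference of means, with every regrouping enumerated. The response and time comparisons permuted labels within day and within response label, and averaged the within-stratum differences. P values were adjusted by Benjamini-Hochberg over the 20 tests of 4 measures in 5 comparisons. V and J usage was the percent of normalized counts per mouse. It was tested with limma 3.58.1 on the log2 of the percent plus 0.1, for segments with a mean usage of at least 0.1%, at an adjusted p threshold of 0.05 over all V and J segments of the fit. The 12 triple-treated mice made 1 fit with 4 group means, and the 12 mice of d95 made 1 fit with 3 treatment means. Overlap between mice was the Morisita-Horn index over clonotypes defined by CDR3 amino acids, V and J. It was tested by an exact permutation of the response labels within day. CDR3 amino acid sequences present in at least 6 of the 12 triple-treated mice were tested with limma on the log2 of counts per 100000 plus 1.

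The segments named were those past the threshold in any of the 5 comparisons, the 5 V and 3 J segments with the largest absolute log2 change in each comparison, and the 5 V segments with the highest mean usage. Fixed lists were the 9 V segments of the block reported as deleted in the FVB strain, 3 V segments used by invariant natural killer T (iNKT) cells, 4 V segments favoured by mucosal-associated invariant T (MAIT) cells, 13 V pseudogenes, and the TRBJ1 and TRBJ2 clusters. The iNKT and MAIT lists hold segments that other T cells use too. As only TRB was sequenced, their shares do not measure iNKT or MAIT cells. The CDR3 sequences named were the 5 present in most mice and, as none passed its test, the 3 with the smallest p. Groups, comparisons, tests, lists and this rule were fixed before the data were examined. A family of 25 exact tests of the lists' shares, 5 lists in 5 comparisons, was added after the levels had been seen and was adjusted as a family of its own.

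Alternatives fixed before the data were examined were the read counts, clonotypes counted once, minimum counts of 2 and 10, merging of clonotypes by amino acid sequence, rarefied counts, other pseudocounts and usage filters, the centred log-ratio, removal of each mouse's largest clonotype, edgeR 4.0.16 with totals and with TMM factors, DESeq2 1.42.0, other strata, other overlap measures, and leaving out each mouse in turn. The other normalized column, removal of the FVB-deleted V segments, removal of 2 doubted libraries (R mouse 2 of d95 and R mouse 3 of d105), removal of each mouse's 10 largest clonotypes, and overlap within each day were chosen after seeing the data. The procedures were tested on simulated data with known differences. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

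Libraries held 31809 to 977897 reads, with a median of 104060. A share of 0 in the shallowest library allows a share of up to the floor of 3 reads in its total. Intervals are Wilson intervals at 95% and, as PCR reads are not independent molecules, they and the floors cover counting error only. The PLX3397 plus PTX group of d105 had 1 mouse with a table and entered no comparison.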

Results

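The data were TRB clonotype tables from the blood of 18 MMTV-PyMT mice in 7 groups. At 95 days of age (d95) these were 3 mice given PTX, 2 given PLX3397 and PTX, and 7 given PLX3397, PTX and anti-PD-1 (triple treatment; 4 with the label R and 3 with NR). At d105 they were 5 triple-treated mice (3 R, 2 NR) and 1 given PLX3397 and PTX. Libraries held 280 to 7147 clonotypes. Libraries of d95 held 31809 to 977897 reads and those of d105 79553 to 674505. In R mouse 2 of d95, 72.4% of clonotypes had 1 read. This share was 17.7% in the lowest library, 32.2% in the median and 53.8% in the next highest, PTX mouse 1 of d95.

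The blood repertoires were polyclonal, with a mean clonality between 0.0661 and 0.141 in the groups with more than 1 mouse. The most used V segments over the 18 mice were TRBV24 at 15.6% ± 2.95 (SD), TRBV4 at 13.8% ± 3.96, TRBV3 at 13.1% ± 2.45, TRBV1 at 12.02% ± 1.54 and TRBV2 at 9.97% ± 1.57. These levels depended on the deposited normalization: by reads, TRBV4 took 6.33% and TRBV1, a V segment also found in iNKT receptors, took 18.2%. None of the 13 V pseudogenes had reads. The largest clonotype of 12 of the 18 mice by normalized counts joined TRBV4 to TRBJ2-7, a pair whose deposited factor was 3.45. By reads 1 of the 18 did, while 5 joined TRBV19 to TRBJ2-7. In 5 others, all of d105, it was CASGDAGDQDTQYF with TRBV13-2 and TRBJ2-5. Of 34124 distinct CDR3 amino acid sequences, 31121 (91.2%) were found in 1 mouse. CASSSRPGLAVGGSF was found in 11 of the 18 mice, and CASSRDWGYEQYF and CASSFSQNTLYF in 10. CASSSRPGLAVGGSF was a trace sequence, with a share of at most 0.00810% in any mouse. It had 2 nucleotide sequences listed with 6 V and J pairs, against 8 with 6 for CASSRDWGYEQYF and 3 with 2 for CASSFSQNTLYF. Carry-over between libraries or wrong segment assignment was not tested for it. A further 4 sequences tied at 9 mice, among them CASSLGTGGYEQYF and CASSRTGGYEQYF.

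The comparison of R with NR mice asked how the blood repertoire differed with the outcome of triple treatment. TRBV19, the main beta segment of MAIT cells beside the TRBV13 family, was lower in R mice, at 7.08% ± 1.97 (SD, n = 7) against 9.53% ± 0.935 (n = 5), a log2 change of -0.51 ± 0.12 (SE). It was below the NR mean of the same day in 7 of 7 R mice (limma adjusted p = 0.0225). TRBJ1-6, a joining segment of the TRBJ1 cluster, was also lower, at 3.49% ± 1.14 against 4.77% ± 0.396, with a log2 change of -0.58 ± 0.13 in 6 of 7 mice (limma adjusted p = 0.0225). Within days, the log2 change of TRBV19 was -0.23 at d95 and -0.78 at d105, and that of TRBJ1-6 was -0.10 and -1.05. The difference between days did not pass its test for either segment (limma adjusted p = 0.171 and 0.0717).

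Limma called these 2 of 27 segments, both lower, and 4 had an unadjusted p under 0.05. Among the 4 tested MAIT segments 1 fell and 3 did not pass, and among the 6 tested TRBJ1 segments 1 fell and 5 did not pass; the counts adjusted over the list alone were also 1 and 1. None of the 3 tested segments of the FVB-deleted block, the 3 iNKT segments or the 6 tested TRBJ2 segments passed, also when adjusted over the list alone. TRBV30 had the largest log2 change without passing, 2.41 ± 0.68, with 1.22% in R and 0.395% in NR mice. The direction was seen in 5 of 7 mice (limma adjusted p = 0.0520). EdgeR and DESeq2 called TRBV30, as did limma by read counts (adjusted p = 0.0361) and with a pseudocount of 0.01% (adjusted p = 0.0324). Without the 10 largest clonotypes of each mouse its change was 1.87 (limma adjusted p = 0.330), and leaving out single mice gave either outcome. The TRBV30 change was 0.83 at d95 and 3.98 at d105, where both NR mice had 0%, so the d105 value was set by the pseudocount. With pseudocounts of 0.01% and 1% the change over both days was 4.51 and 0.79. The other V segments among the 5 with the largest changes were TRBV23 at -1.20, TRBV13-3 at 0.74 and TRBV4 at -0.37, and the other J segments among the 3 largest were TRBJ2-4 at 0.27 and TRBJ1-4 at -0.25. The lowest limma adjusted p of these 5 was 0.337. Both calls were lost with each clonotype counted once and with the centred log-ratio, and TRBJ1-6 also with edgeR and TMM factors. They were lost too without R mouse 1, 2 or 4 of d95 or NR mouse 3 or 4 of d105, each of which left 0 segments past the threshold and 3 to 5 at an unadjusted p under 0.05. Over 27 alternative settings the log2 change stayed between -0.61 and -0.42 for TRBV19 and between -0.66 and -0.093 for TRBJ1-6.

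**Figure D1:**
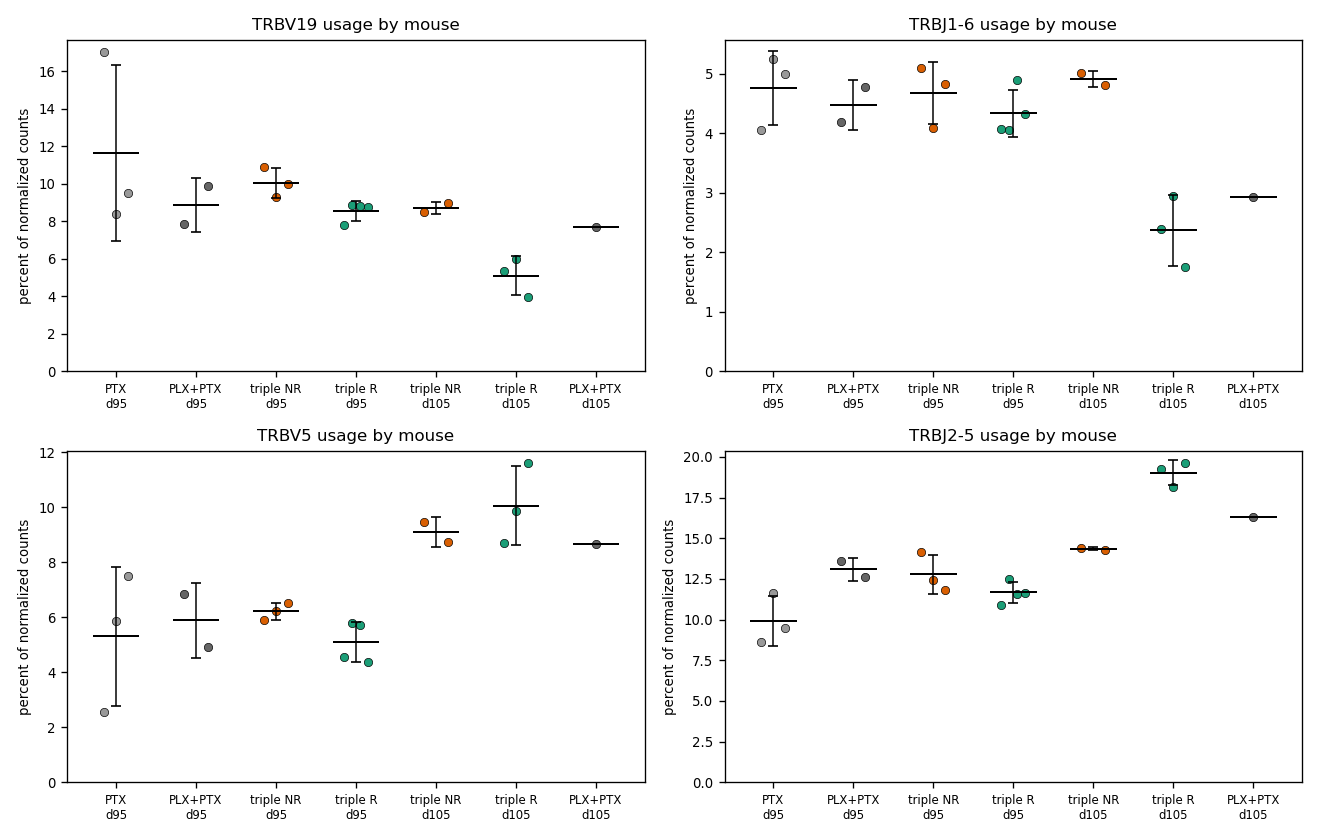
Usage of TRBV19, TRBJ1-6, TRBV5 and TRBJ2-5 in percent of normalized counts, by group and day; points are mice, horizontal lines group means and bars 1 SD, with no bar for the group of 1 mouse. TRBV19 was 5.11% on average in R mice of d105 and 8.73% in NR mice of d105.

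Clonality was higher in R than in NR mice by 0.0308 ± 0.0302 (SE), averaged over days, which did not pass (exact permutation p = 0.449, adjusted p = 1). The difference rested on few libraries: it was 0.00850 without R mouse 2 of d95, whose clonality was 0.267, and 0.0118 without R mouse 3 of d105. Rarefied richness differed by 283 clonotypes ± 619 (exact p = 0.694), the share of the 10 largest clonotypes by -3.76 points ± 3.61 (exact p = 0.437) and CDR3 length by -0.0137 amino acids ± 0.0915 (exact p = 0.846); each adjusted p was 1. At d95 the differences were 0.0674 in clonality, -317 in richness and 2.06 points in the top-10 share; at d105 they were -0.00586, 883 and -9.57. The smallest p this design allows is 0.00286, which alone would be 0.0571 after adjustment, so no single measure could pass.

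The mean Morisita-Horn index was 0.0316 over 13 pairs with the same label and 0.0370 over 18 pairs with different labels, within days (difference -0.00546, two-sided exact permutation p = 0.611). Of these pairs, 4 and 6 were of d105, so the pooled difference also reflects the mix of days. Overlap was far higher at d105, with a mean of 0.0981 (0.0545 to 0.199, 10 pairs) against 0.00457 (0.000191 to 0.0252, 21 pairs) at d95. Without the clonotypes of the FVB-deleted V segments these means were 0.00104 and 0.00456, so the higher overlap at d105 lay in that block, to which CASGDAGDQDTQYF belongs. The difference between same and different labels was -0.00285 at d95 (exact p = 0.314) and -0.00351 at d105 (exact p = 0.9, smallest possible 0.1). Without the FVB-deleted V segments it was -0.00286 at d95 and 0.000874 at d105 (exact permutation p = 0.314 and 0.5). Over both days and with all V segments, the exact p was 0.0476 without R mouse 1 of d105, with more overlap between different labels. Of 8 CDR3 sequences present in at least 6 of the 12 mice, limma called 0, and 0 had an unadjusted p under 0.05. In simulations, sequences changed 2-fold were called in 1%, 8-fold in 13% and 32-fold in 50%, so these tests would miss most moderate changes. The smallest p belonged to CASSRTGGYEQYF (log2 change 1.54 ± 1.77), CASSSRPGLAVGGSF (-0.88 ± 1.09) and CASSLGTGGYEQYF (-1.40 ± 2.15), each with a limma adjusted p of 0.724. No other tool was run on these sequences.

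The comparison of triple-treated mice at d105 with those at d95 asked how the blood repertoire differed at the later time. TRBV13-2, a segment used by iNKT cells and found in the block reported as deleted in FVB mice, rose from 0.0651% ± 0.129 (SD, n = 7) to 3.31% ± 1.96 (n = 5), a log2 change of 4.47 ± 0.50 (SE). Its d95 level lay below the pseudocount, and over the alternative settings the log2 change ranged from 1.76 with each clonotype counted once to 6.65 with a pseudocount of 0.01%. Much of the rise by counts lay in 1 TRBV13-2 sequence, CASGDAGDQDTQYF, whose source is open. It took 0.956% (R mouse 2) to 4.82% (R mouse 3) of reads in the 5 d105 mice. In R mouse 2 it held 0.9286% of normalized counts, against 0.9288% for all of TRBV13-2. TRBV5 rose from 5.58% ± 0.810 to 9.67% ± 1.18 (0.75 ± 0.11), and TRBJ2-5 from 12.2% ± 1.03 to 17.2% ± 2.62 (0.43 ± 0.08). TRBV19 fell from 9.20% ± 0.996 to 6.56% ± 2.12 (-0.48 ± 0.12). Each direction was seen in 5 of 5 d105 mice, and the limma adjusted p values were 1.5e-04, 9.7e-04, 0.0043 and 0.0149. All mice of a day share their collection time, so day and any processing batch cannot be told apart.

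Limma called these 4 of 27 segments, 3 higher and 1 lower, with 10 at an unadjusted p under 0.05. In the FVB-deleted block 1 of 3 tested segments rose and 2 did not pass, and adjusted over the list alone all 3 rose, TRBV13-1 and TRBV13-3 beside TRBV13-2. These 3 are also MAIT segments: among the 4 of that list 1 rose and TRBV19 fell, and 3 rose and 1 fell when adjusted over the list alone. TRBV13-2 was also the 1 of 3 iNKT segments that rose, by both adjustments, so every rise in these 2 lists lay in the deleted block. No TRBJ1 segment passed, while TRBJ1-1 and TRBJ1-6 fell when adjusted over the list alone, and 1 of 6 TRBJ2 segments rose by both adjustments. Not passing over all segments were TRBV13-3 (log2 change 2.42), TRBV13-1 (1.495), TRBV30 (-0.72), TRBJ1-4 (-0.51) and TRBJ1-6 (-0.40), with limma adjusted p of 0.0674 or more. EdgeR and DESeq2 called the first 3, with a log2 change of TRBV30 from -5.62 to -4.86. By limma the TRBV30 change was -1.29 without NR mouse 2 of d95, -0.41 without NR mouse 3 of d95 and -0.22 by read counts. With clonotypes of the FVB-deleted V segments left out, 2 segments passed, TRBV5 and TRBV19, and the log2 change of TRBJ2-5 was 0.18 (limma adjusted p = 0.206). The centred log-ratio moved the median change of all segments by -0.41 and called 8, 2 higher and 6 lower; it ended the TRBV5 call, and counting each clonotype once ended those of TRBV5, TRBJ2-5 and TRBV19. The TRBV19 call was also lost without NR mouse 3 of d105. Over the alternative settings the log2 change ranged from 0.33 to 0.90 for TRBV5, from 0.16 to 0.61 for TRBJ2-5 and from -0.89 to -0.25 for TRBV19. Without the 10 largest clonotypes of each mouse only TRBV5 passed, and the log2 change of TRBV13-2 was 1.98 (limma adjusted p = 0.0634).

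The labels do not give the strain background of the mice. The FVB-deleted block as a whole took 0.0189% to 0.719% of reads in the 12 libraries of d95 and 0.709% to 14.4% in the 6 of d105. Among triple-treated mice its share of normalized counts was 5.72 points ± 2.32 (SE) higher at d105. By share of clonotypes the block took a mean of 0.459% in R and 0.451% in NR mice at d95, and 3.18% and 3.59% at d105. By normalized counts R mouse 3 of d105 had 14.2%. The difference of 5.72 points was 3.66 without it, 3.72 without both doubted libraries and 3.32 with the other normalized column. The exact permutation p was 0.00286, the smallest possible, and 0.0714 after adjustment over the 25 tests of list shares, so it did not pass, and no test of this design could have passed alone; 0 of these 25 tests passed and 4 had an unadjusted p under 0.05, of which the TRBJ1 and TRBJ2 shares over time are 1 result, as they sum to 100%. The CDR3 sequence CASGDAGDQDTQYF, carried by TRBV13-2 and TRBJ2-5, was found in all 6 d105 libraries, at 0.253% to 4.82% of reads. It was also found in 2 of the 12 d95 libraries, R mouse 2 (252 reads, 0.330%) and R mouse 3 (2 reads).

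**Figure D2:**
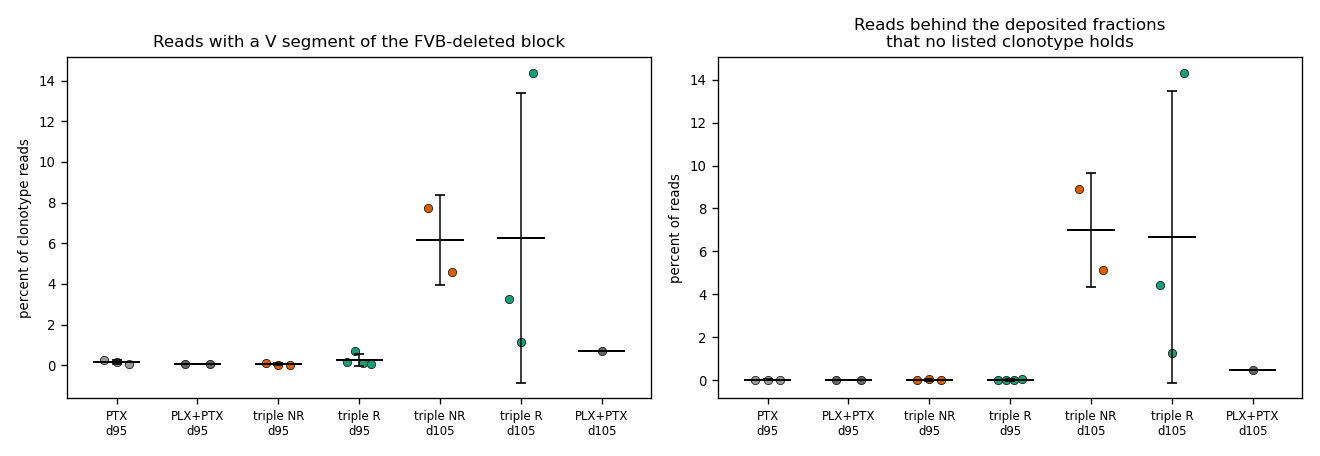
Percent of clonotype reads with a V segment of the FVB-deleted block (left) and percent of the reads behind the deposited fractions that no listed clonotype holds (right), by group and day; points are mice, horizontal lines group means and bars 1 SD. Both measures were at most 0.719% in the 12 libraries of d95 and reached 14.4% and 14.3% at d105.

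The 10 largest clonotypes held 10.9 points ± 3.61 (SE) more of the counts at d105, 16.7 points in NR and 5.11 in R mice. This and clonality cover listed clonotypes only. Clone number 0 was not listed in 6 of 6 libraries of d105 and 6 of 12 of d95, and the unlisted reads exceeded the largest listed clonotype in 6 of 6 and 0 of 12. The exact permutation p of the top-10 share was 0.0343 and did not pass adjustment over the 20 tests (adjusted p = 0.686). Its difference was 9.18 points without the FVB-deleted V segments (exact p = 0.0571) and 7.86 without both doubted libraries (exact p = 0.11). Leaving out single mice, it ranged from 7.67 without R mouse 3 of d105 (exact p = 0.113) to 13.2 without R mouse 2 of d105 (exact p = 0.00667). Clonality differed by 0.0379 ± 0.0302 (exact p = 0.266), rarefied richness by -972 clonotypes ± 619 (exact p = 0.223) and CDR3 length by -0.0286 amino acids ± 0.0915 (exact p = 0.691), each with an adjusted p of 1. The clonality difference was 0.00126 in R and 0.0745 in NR mice. It was 0.0601 without R mouse 2 of d95 and 0.0189 without R mouse 3 of d105. The top-10 share also went with depth within days: over the 12 libraries of d95 its correlation with log10 reads was r = -0.779 (permutation p = 0.0033) and rho = -0.853 (permutation p = 6.6e-04), with an adjusted p of 0.0194 for r over 14 relations. Without the 2 libraries farthest from the median depth r was -0.798. Over the 6 libraries of d105, r was -0.971 (exact permutation p = 0.025, adjusted p = 0.05), rho was -0.886 (exact permutation p = 0.0333), and r was -0.947 without the 2 farthest libraries. Richness and clonality also went with depth: richness over the libraries of d95 (r = 0.781, adjusted permutation p = 0.0194; 0.71 without the 2 farthest) and clonality over those of d105 (r = -0.859, adjusted exact permutation p = 0.0243). The top-10 share went with the number of listed clonotypes too, with r = -0.661 at d95 and -0.974 at d105 (adjusted permutation p = 0.0398 and 0.0194). Mean reads were 64363 at d95 and 442284 at d105 in R mice, and 158394 and 103204 in NR mice. In R mice depth was thus higher at d105, where the relation within days would give a lower top-10 share.

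**Figure D3:**
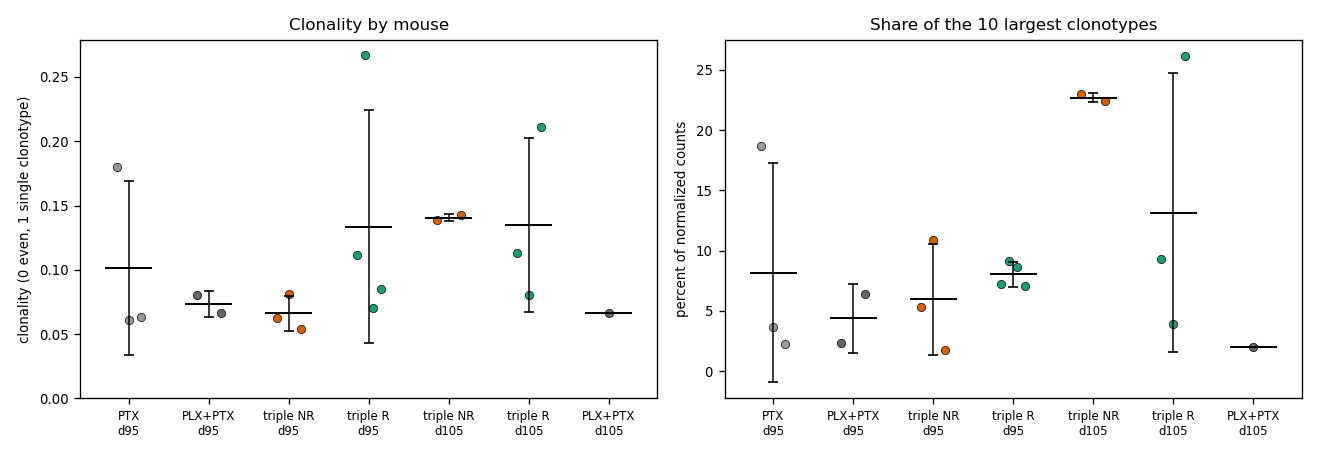
Clonality (left, from 0 for even clonotypes to 1) and the share of the 10 largest clonotypes in percent of normalized counts (right), by group and day; points are mice, horizontal lines group means and bars 1 SD. The 2 NR mice of d105 had a mean top-10 share of 22.7%, against 5.97% in the 3 NR mice of d95.

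The comparison of triple-treated mice with those given PLX3397 and PTX at d95 asked what adding anti-PD-1 changed. TRBV1 was 12.9% ± 1.26 (SD, n = 7) with and 12.4% ± 0.515 (n = 2) without anti-PD-1, and TRBV19 was 9.20% ± 0.996 and 8.87% ± 1.44. The largest log2 changes were those of TRBV30 (-0.77, but -0.31 without NR mouse 2), TRBV23 (-0.49), TRBV20 (0.45), TRBV4 (-0.42), TRBV2 (0.17), TRBJ1-4 (-0.21), TRBJ1-3 (-0.19) and TRBJ2-1 (0.19). Limma, edgeR and DESeq2 called 0 of 24 segments, and limma found 0 at an unadjusted p under 0.05 (lowest limma adjusted p = 0.982). No tested segment of the iNKT, MAIT, TRBJ1 or TRBJ2 lists passed, also adjusted over the list alone, and no segment of the FVB-deleted block reached the usage minimum. Clonality differed by 0.0311 ± 0.0288 (SE, exact permutation p = 0.556), or 0.00399 without R mouse 2 of d95, richness by -518 ± 1159 (exact p = 0.722), the top-10 share by 2.75 points ± 2.31 (exact p = 0.306) and CDR3 length by 0.0360 ± 0.0365 (exact p = 0.5). The smallest p with 7 and 2 mice is 0.0278.

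The comparison of PLX3397 and PTX with PTX alone at d95 asked what CSF1R inhibition changed. TRBJ2-5 was 13.1% ± 0.71 (SD, n = 2) with and 9.92% ± 1.53 (n = 3) without PLX3397, a log2 change of 0.41 ± 0.15 (SE) in 2 of 2 mice. It did not pass (limma adjusted p = 0.447) but was called by DESeq2. TRBV1, of the iNKT list, was 12.4% ± 0.515 and 10.0% ± 1.11, and TRBV19, of the MAIT list, was 8.87% ± 1.44 and 11.6% ± 4.69. Other large log2 changes were those of TRBV20 (1.60, but -0.11 without PTX mouse 1), TRBV23 (1.19), TRBV26 (-0.32), TRBJ1-5 (0.43) and TRBJ1-2 (-0.33). Limma and edgeR called 0 of 24 segments and DESeq2 called 1, with 1 at an unadjusted p under 0.05 by limma. No list had a member that passed, also adjusted over the list alone. The iNKT segments together held 3.31 points ± 0.721 more of the counts with PLX3397 (exact permutation p = 0.1, the smallest possible). By share of clonotypes they held 22.7% with and 20.6% without PLX3397. Clonality differed by -0.0278 ± 0.0398, richness by 394 ± 1261, the top-10 share by -3.79 points ± 5.63 and CDR3 length by 0.0198 ± 0.0516, with exact permutation p values of 1, 0.7, 0.9 and 0.9. With 2 and 3 mice the smallest p is 0.1, so these 4 tests could not pass.

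The comparison of triple treatment with PTX alone at d95 asked what adding both PLX3397 and anti-PD-1 changed. TRBV1, of the iNKT list, was 12.9% ± 1.26 (SD, n = 7) in triple-treated and 10.0% ± 1.11 (n = 3) in PTX mice, a log2 change of 0.36 ± 0.11 (SE) seen in 7 of 7 mice. It did not pass over all segments (limma adjusted p = 0.154) and passed when adjusted over the list alone (limma adjusted p = 0.0128), where 1 of 2 tested iNKT segments rose; with each clonotype counted once its change was -0.0074. TRBJ2-5 was 12.2% ± 1.03 and 9.92% ± 1.53, higher in 7 of 7 mice (limma adjusted p = 0.265). Other large log2 changes were those of TRBV20 (2.05, but 0.34 without PTX mouse 1, which had 0%), TRBV30 (-1.07, but -0.50 without PTX mouse 1 and -0.61 without NR mouse 2), TRBV23 (0.70), TRBV4 (-0.33), TRBJ1-2 (-0.30) and TRBJ1-5 (0.30). Limma, edgeR and DESeq2 called 0 of 24 segments, with 3 at an unadjusted p under 0.05 by limma. The MAIT, TRBJ1 and TRBJ2 lists had no member that passed, also adjusted over the list alone. The iNKT segments together held 3.61 points ± 0.819 (SE) more of the counts in triple-treated mice (exact permutation p = 0.0167, adjusted p = 0.143 over the 25 tests of list shares), which did not pass, and 0.307 points with each clonotype counted once (exact p = 0.808). This is a share of V segments and not of iNKT cells. Clonality differed by 0.00325 ± 0.0482 (exact p = 0.95), richness by -124 ± 828 (exact p = 0.858), the top-10 share by -1.04 points ± 5.37 (exact p = 0.825) and CDR3 length by 0.0558 ± 0.0484 (exact p = 0.2).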

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

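The tests below were chosen after the result was seen; the bounds for library depth (TRBV19), for the 10 largest clonotypes and for sequencing errors were set out before their values were known.

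Reads of V segments in the FVB-deleted block were far more frequent at d105, and so were reads missing from the tables. The reads behind the deposited fractions that no listed clonotype holds were at most 0.0797% in the 12 libraries of d95, and 0.493% to 14.3% in the 6 of d105. Over those 6 libraries they went with the block's share of reads (r = 0.993, exact permutation p = 0.00139; rho = 1, exact permutation p = 0.00278; r = 0.982 without the 2 farthest libraries). In the median d105 library 71.9% of the block's reads lay in nucleotide CDR3 sequences also found in another d105 library, against 2.07% of its other reads. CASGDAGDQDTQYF alone held 33.5% (R mouse 3) to 84.8% (R mouse 2) of the block's reads, and all of the shared part in NR mouse 4 (67.2%). The sharing thus rests in large part on 1 sequence. The share therefore cannot tell the mice's own T cells with an undeleted locus from a common source of DNA. Mice whose own T cells carried that 1 sequence would give a high share too. A common source of DNA in the d105 libraries may account for the shared sequences. However, 1 of them, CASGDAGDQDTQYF, was also found in 2 of the 12 d95 libraries. Whether the unlisted reads have the same source stays open.

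Lower TRBV19 and TRBJ1-6 usage in R mice was weighed against chance, depth and a few large clonotypes. Of 100 splits of the 12 mice, the real one included, 5 gave as many segments as the real 2 (highest other 3), so chance was not excluded. With log10 reads as a covariate the log2 changes were -0.53 for TRBV19 and -0.61 for TRBJ1-6, so a linear effect of read depth does not account for either. The number of listed clonotypes was not used as a covariate. Without the 10 largest clonotypes of each mouse the changes were -0.56 for TRBV19 and -0.53 for TRBJ1-6, which argues against these clonotypes as the source. With each clonotype counted once they were -0.45 and -0.093, so expanded clonotypes below the 10 largest stay open for TRBJ1-6, as does an untested difference in T cell composition between responding and non-responding mice.

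In R mouse 2 of d95, 4724 clonotypes (72.4%) had 1 read. Of these, 4.36% were found with the same nucleotide CDR3 in another library, against 1.49% to 14.3% in the other 17 libraries. This argues against listed clonotypes of those 17 libraries as the source of most of them. The 31 samples without a table and unlisted clonotypes could not be searched. Of the 4724 clonotypes, 0.381% lay at 1 base from a larger clonotype of the same library. This share was 1.18% to 24.2% in the others, which argues against single-base errors of larger listed clonotypes as the source of most of them. Errors at more than 1 base and joined fragments of different clonotypes were not searched for. No biological explanation was tested.

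For TRBV20 the difference between R and NR mice differed between days, by 1.92 on the log2 scale (limma adjusted p = 0.0377). By normalized counts it took 5.54% in R and 3.21% in NR mice at d95, and 2.65% and 5.97% at d105. By share of clonotypes these means were 1.41% and 1.58% at d95 and 1.15% and 1.31% at d105, lower in R mice on both days. TRBV20 usage also depended on the normalization, with a mean over the 18 mice of 3.70% by normalized counts and 1.66% by reads. Over time, 1 of 100 splits, drawn from 350 possible, gave as many segments as the real 4, and it was the real one (highest other 1). A count of 4 was thus rare among the splits drawn, although day and batch stay one. Splits were not run without the FVB-deleted V segments, where 2 segments were called. For triple-treated against PTX mice the real count was 0 segments (highest other 2), and for shared CDR3 sequences it was 0 (highest other 1). A count of 0 is reached by all 100 splits whatever the data, so these splits say nothing about chance.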

How the results depend on the processing

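The other normalized column, the removal of the FVB-deleted V segments, the removal of both doubted libraries, the removal of each mouse's 10 largest clonotypes, overlap within each day and the tests of list shares were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers that link mice. No clonotype was left out as unproductive, since all were productive, but those with a normalized count of 0 did not enter the main values. A minimum of 9 of 12 mice left 0 shared CDR3 sequences to test. Of 377 alternative values of the 20 tests of measures per mouse, 344 kept their direction and 33 were reversed. The lowest adjusted p was 0.133; a test of response or time at its smallest p would alone be 0.0571 after adjustment, so the absence of a pass says little. Limma called 0 segments for response with each clonotype counted once and with the centred log-ratio, and 0 to 3 without 1 mouse each. For time, against the 3 higher and 1 lower segments, it called 7 with the other normalized column (3 higher, 4 lower), 8 with the centred log-ratio (2 higher, 6 lower), 2 without the FVB-deleted V segments and 1 (TRBV5) without the 10 largest clonotypes of each mouse. EdgeR with totals, edgeR with TMM and DESeq2 each called 7 for time (5 higher, 2 lower). Without 1 mouse each, limma called 3 to 10 for time, with 7 without NR mouse 4 and 10 without R mouse 2 of d105. DESeq2 called 1 segment for PLX3397, TRBJ2-5. Of the 25 tests of list shares, 3 passed without NR mouse 2 of d95 and 0 in every other setting run; 2 of the 3, the TRBJ1 and TRBJ2 shares over time, are 1 result with the sign turned. The settings of the 6 calls kept TRBV13-2 over time in 25 of 26, TRBV5 in 25 of 27, TRBJ2-5 and TRBV19 over time in 24 of 27, TRBV19 for response in 20 of 27 and TRBJ1-6 in 19 of 27. Depth limits what can be seen: the shallowest library held 31809 reads.

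Values whose direction was reversed follow, with segments as log2 changes, shares in percentage points and comparisons named by what was added or compared (both drugs: PLX3397 and anti-PD-1 added to PTX). The cause was not tested. Without clonotypes of a count under 10, clonality was -0.00709, richness -91.6 for response. For both drugs, clonality was -0.00347. With rarefied counts, clonality was -0.00408 for both drugs. At full depth, richness was 121 for both drugs. With each clonotype counted once, CDR3 length was 0.0179, TRBV1 -0.042, FVB-deleted block share -0.200, iNKT share -0.458, TRBJ1 share 0.433, TRBJ2 share -0.433 for response. For anti-PD-1, CDR3 length was -0.0787, TRBJ1-4 0.037, TRBV1 -0.16, TRBV19 -0.023, TRBV23 0.027, iNKT share -1.80, TRBJ1 share 0.0309, TRBJ2 share -0.0309. For both drugs, CDR3 length was -0.00338, TRBV1 -0.0074, TRBV24 -0.15, TRBV4 0.070. For time, TRBJ1-6 was 0.029, TRBV1 0.0032, TRBV24 0.19, TRBV4 -0.21, iNKT share -1.18. For PLX3397, TRBV2 was 0.0092. In d95 alone, richness was -317, top-10 share 2.06 for response. In d105 alone, clonality was -0.00586 for response. Without both doubted libraries, clonality was -0.0105, overlap 0.000788, TRBV13-3 -0.011, TRBV4 0.066, FVB-deleted block share -1.88 for response. For both drugs, clonality was -0.0238, TRBV3 -0.042, FVB-deleted block share -0.0678. For anti-PD-1, TRBJ1-6 was 0.020, iNKT share -0.0397. With the centred log-ratio, TRBV24 was -0.0071 for response. For time, TRBV4 was -0.33. For anti-PD-1, TRBJ1-6 was 0.011, TRBV3 0.083, TRBV5 0.018. For PLX3397, TRBV3 was -0.19, TRBV4 -0.13. For both drugs, TRBV2 was -0.065, TRBV24 -0.11, TRBV3 -0.10. With DESeq2, TRBV13-2 was 0.55, TRBV5 0.045 for response. For anti-PD-1, TRBV19 was -0.0066, TRBV3 0.0058. For both drugs, TRBV24 was -0.065. With the other normalized column, TRBV5 was 0.021 for response. For anti-PD-1, TRBJ1-6 was 0.047. For both drugs, TRBJ1-6 was 0.0089, TRBV24 -0.022. For time, iNKT share was -0.463. With edgeR totals, TRBV13-2 was 0.41 for response. For anti-PD-1, TRBV19 was -0.011. For PLX3397, TRBV2 was 0.00014. For both drugs, TRBV24 was -0.049. With edgeR TMM, TRBV13-2 was 0.40 for response. For anti-PD-1, TRBJ1-3 was 0.0081, TRBJ1-6 0.022, TRBV3 0.022. For both drugs, TRBV24 was -0.063. Without the 10 largest clonotypes of each mouse, TRBJ2-4 was -0.087, TRBV4 0.25 for response. For time, TRBV1 was 0.049, TRBV3 0.0097, TRBV4 -0.088. For anti-PD-1, TRBJ1-6 was 0.038, TRBV3 0.038. For PLX3397, TRBV26 was 0.037, TRBV3 -0.023. Without the largest clonotype of each mouse, TRBV4 was -0.055 for time. For anti-PD-1, TRBJ1-6 was 0.0022, TRBV3 0.00083. For response, FVB-deleted block share was -0.976. By read counts, TRBV19 was -0.0058, MAIT share -0.00917 for anti-PD-1. For both drugs, TRBV24 was -0.037. For time, iNKT share was -0.0243. Without 1 mouse each, the ranges for response were richness -12.0 to 736, CDR3 length -0.0817 to 0.0542, overlap -0.0132 to 0.00404, TRBV13-3 -0.13 to 1.61, TRBV24 -0.020 to 0.20, FVB-deleted block share -1.82 to 1.48. Without 1 mouse each, the ranges for both drugs were richness -737 to 445, top-10 share -4.00 to 4.19, clonality -0.0238 to 0.0425, TRBV19 -0.47 to 0.036, TRBV23 -0.069 to 1.30, TRBV24 -0.19 to 0.22, TRBV3 -0.042 to 0.10, TRBV5 -0.26 to 0.50, FVB-deleted block share -0.0678 to 0.0647, MAIT share -4.12 to 0.308. Without 1 mouse each, the ranges for anti-PD-1 were richness -1578 to 542, TRBJ1-6 -0.10 to 0.091, TRBV19 -0.11 to 0.22, TRBV2 -0.058 to 0.40, TRBV24 -0.0016 to 0.13, TRBV3 -0.082 to 0.060, TRBV5 -0.31 to 0.17, iNKT share -0.168 to 0.760, MAIT share -0.606 to 1.41, TRBJ1 share -2.91 to 0.795, TRBJ2 share -0.795 to 2.91. Without 1 mouse each, the ranges for PLX3397 were richness -666 to 1454, CDR3 length -0.0162 to 0.0578, clonality -0.0479 to 0.0114, top-10 share -6.75 to 1.44, TRBJ1-6 -0.19 to 0.012, TRBV2 -0.33 to 0.13, TRBV20 -0.11 to 2.59, TRBV24 -0.25 to 0.16, TRBV26 -0.67 to 0.031, TRBV5 -0.19 to 0.57, TRBJ1 share -1.99 to 1.72, TRBJ2 share -1.72 to 1.99. Without 1 mouse each, the ranges for time were CDR3 length -0.0965 to 0.0394, TRBV4 -0.15 to 0.41.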

Other observations

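The test of recombination below was chosen after its result was seen.

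CDR3 sequences found in several mice were shorter than those found in 1 mouse, in 18 of 18 mice, by a mean of -0.605 amino acids ± 0.0985 (SD; 13.5 against 14.1). A candidate explanation is that shared sequences are easier to make by recombination, which would give them more nucleotide sequences per amino acid sequence at equal length. This was so in 14 of 18 mice (means 1.09 and 1.05), fewer than the bound of 15 set for the test, so the hypothesis stays undecided. The mice hold the same shared sequences and are not independent of each other, so no p is given for either count.

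The mouse given PLX3397 and PTX at d105, alone in its group, had 674505 reads, 7147 clonotypes, a clonality of 0.0665 and a top-10 share of 2.02%. TRBV5 took 8.66% of its counts, TRBV19 7.68%, TRBJ2-5 16.3% and TRBJ1-6 2.94%. The FVB-deleted block took 0.709% of its reads (95% Wilson interval 0.69 to 0.73), the lowest share of the 6 libraries of d105.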
